A study of Homo sapiens with 8 samples.

How the data were processed

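RNA of SKOv3 cells was extracted with Trizol and labelled with biotin for Affymetrix whole-transcript arrays, per the labels. The groups, miR-378 mimic and negative control with 4 arrays each, were taken from the sample titles. The deposited values are expression levels, 1 row per probe, from processing that lists GCOS, Partek 6.2 and RMA, per the submitters' processing notes. RMA corrects background, normalizes the arrays to each other and summarizes probes; the notes give neither order nor settings. The log base is not stated. It was taken as 2 because RMA writes log2 values and the deposited ones lay between 1.90 and 14.16, so each log2 difference and fold here rests on that reading. The genome build and probe annotation behind the values are not given in the sources used here, and no coordinates are printed.

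The value table held 28869 probes. Of these, 19310 carried 1 gene symbol, 1752 several and 7807 were not listed with a symbol in the platform annotation used. Gene IDs of 19279 probes with 1 symbol matched the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 31 did not; 0 symbols changed. A gene was represented by its probe with the highest mean over the 8 arrays, which applied to 685 genes with several probes and left 18377 genes to test. Probes with several symbols or none were kept out of all named results. No gene was filtered for low level in the main test, since the table carries no detection calls. The 28 pairs of arrays correlated with r between 0.989 and 0.998 across genes, which are not independent replicates, and the SD of the difference between a pair ranged from 0.149 to 0.333, so no array repeated another. Array medians over all probes lay between 5.04 and 5.21, and the number of arrays, not a read depth, sets the precision.

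Genes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values, two-sided, without a block, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p under 0.05. A total of 10.7 degrees of freedom stood behind each test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over 29 lists, and again with an estimated correlation and with fry. Lists were matched to tested genes through older and newer symbols, and members with no tested probe, such as TUSC2 and PIK3CA, were not analysed here. An exact two-sided permutation test of each list's mean per array used all 70 orders of the labels. The smallest p that this exact permutation test allows is 0.0286, 2 lists reached it, and the lowest adjusted permutation p over the lists was 0.355. At this floor a list could pass after adjustment only if many of the 29 reached it, so the adjusted value decides nothing.

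Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named by this rule were the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose mean level was at or above the 40th percentile, 5.22. Small RNA genes and symbols starting with LOC were kept out of these and only counted; 2 of them passed. Up to 4 passing members of each list were named, or, where none passed, the member with the smallest p. ALCAM, EHD1, PPARGC1B, ERBB2, VEGFA and SUFU were always named, as would have been MIR378A and TUSC2. Other list members named in the text were chosen after their values were seen. ALCAM and EHD1 were in the lists and in the rule from general knowledge of earlier reports on miR-378, not from the labels.

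The steps were tested on simulated arrays of the same 18377 genes. Of 100 genes changed by 1 on the log2 scale 96% were recovered, and of 100 changed by 0.5 60% were, with 11 false calls; with no change there were 0 calls. Of 100 unshifted lists 3 had a camera p under 0.05. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes move together. Alternatives were a second quantile normalization, subtracting array medians, leaving out dim genes, the replicate number as a block, leaving out each array, a trended and robust eBayes, array weights, other probe rules, a plain equal-variance test and stricter thresholds. Leaving out control replicates 1 and 2 together was added after seeing the data. A planned test of miR-378 seed matches in 3′ UTRs was not run, as transcript sequences were not used here. Figures were drawn with matplotlib 3.10.9.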

Results

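Gene expression was measured on 8 arrays of SKOv3 cells, a human ovarian carcinoma line. In 4 arrays the cells had been transfected with a mimic of miR-378, a synthetic RNA that acts in place of the mature microRNA, and in 4 with a negative control. MicroRNAs lower the levels of messenger RNAs that pair with them, and the comparison asks which genes differ between the groups. The labels do not say which arm of miR-378 the mimic carried. Values are the deposited log2 levels of 18377 genes, and they ranged from 1.90 to 14.16 on this scale. The number of arrays limits the precision. The labels number the arrays of each group without saying that they came from separate cultures, so p-values here measure only the spread between these arrays, which may be technical. MIR378A and TUSC2 were not analysed here. PPARGC1B, the gene that hosts miR-378, had a log2 value of 6.18 ± 0.17 (SD, n = 4) in control and 6.18 ± 0.18 (SD, n = 4) in mimic arrays, a difference of 0.01 whose sign turned when single arrays were left out.

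HIPK3, a homeodomain-interacting protein kinase, rose the most among the genes named by rule, from a log2 value of 7.81 ± 0.14 (SD, n = 4) in control to 8.96 ± 0.03 (SD, n = 4) in mimic arrays. This was a rise of 1.15 (SE 0.0762, adjusted p = 0.000130), or 2.22-fold, on probe 7939197. ELK3, a transcription factor of the ETS family, fell the most, from 8.72 ± 0.04 (SD, n = 4) to 7.68 ± 0.06 (SD, n = 4). Its log2 difference on probe 7957665 was -1.04 (SE 0.0627, adjusted p = 9.43e-05). In all, 65 genes were higher and 42 were lower in mimic arrays by limma's moderated test with Benjamini-Hochberg adjustment, and 17 and 12 of them changed by at least 1.5-fold.

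Among the other genes that rose, radixin (RDX), which ties actin filaments to the cell membrane, rose by 0.95, and ERLIN1, a lipid-raft protein of the endoplasmic reticulum, by 0.85. The Argonaute gene AGO4 rose by 0.72, SAR1B, a GTPase of vesicles leaving the endoplasmic reticulum, by 0.71, and PKIA, an inhibitor of protein kinase A, by 0.71. IL6ST, the signalling receptor chain shared by the interleukin-6 family, rose by 0.67. YWHAH, a phosphoserine-binding adaptor, rose by 0.64, RP2 by 0.63, the phosphate exporter gene XPR1 by 0.63, the importin gene IPO11 by 0.61 and the adhesion molecule ALCAM by 0.61.

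Among the genes that fell, RBBP9, a serine hydrolase that binds the retinoblastoma protein, had a log2 difference of -0.99 and NHSL3 of -0.78. ANKRD52, a regulatory subunit of a protein phosphatase, stood at -0.76, C4orf46 at -0.72 and TUFT1 at -0.71. RPN2, a subunit of the enzyme that attaches N-glycans in the endoplasmic reticulum, fell from 10.17 ± 0.08 (SD, n = 4) to 9.46 ± 0.03 (SD, n = 4), a difference of -0.71. EHD1, which acts in endocytic recycling, stood at -0.70, DAZAP2 at -0.66, the kinase gene PIM2 at -0.64, TMEM245 at -0.61 and CYP1A1, an enzyme of xenobiotic metabolism, at -0.59.

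**Figure D1:**
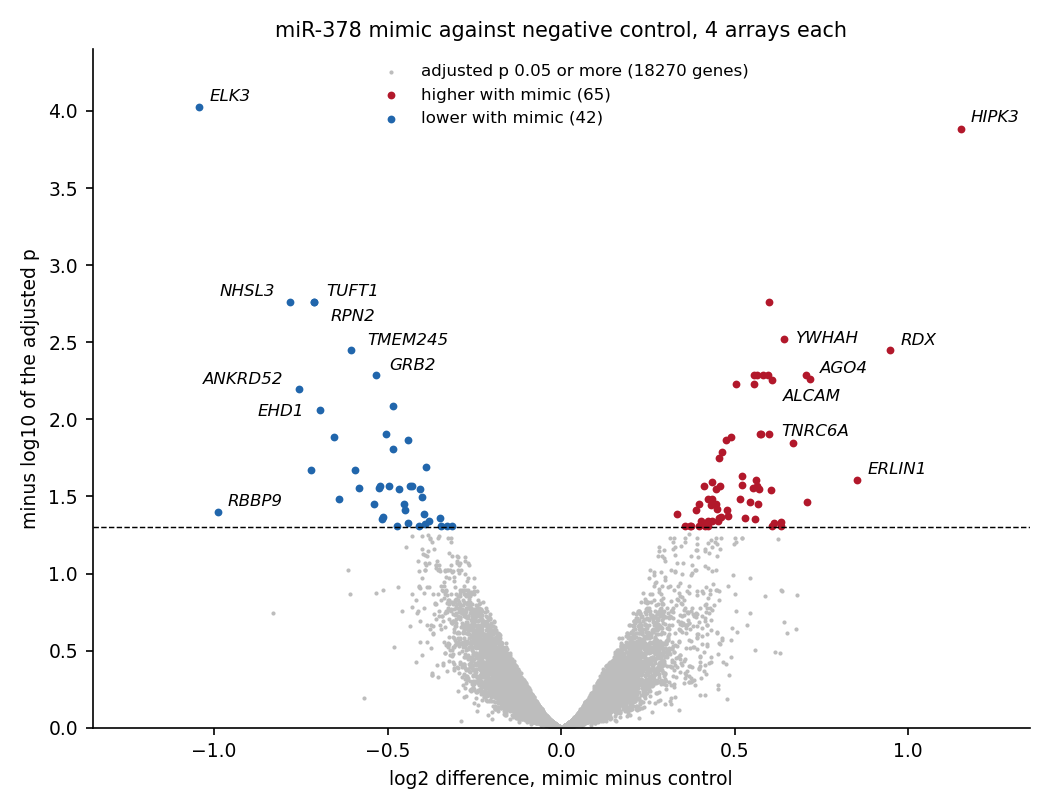
Each point is 1 of 18377 genes; the x axis gives the log2 difference of mimic minus control arrays and the y axis minus log10 of limma's adjusted p, with the dashed line at 0.05. The 65 genes above the line on the right were higher and the 42 on the left lower in mimic arrays, with HIPK3 at 1.15 and ELK3 at -1.04 farthest out.

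In each of the 107 genes the 4 mimic arrays lay on one side of the 4 control arrays. Over all 18377 genes 8.67% were separated in this way, where chance gives 2.86%. At an unadjusted p under 0.05 there were 1057 genes higher and 1216 lower. Of the 30 named genes that passed, 13 kept their call whichever array was left out: HIPK3, RDX, AGO4, PKIA, YWHAH, ALCAM, ELK3, NHSL3, ANKRD52, TUFT1, RPN2, TMEM245 and GRB2. The other 17 kept their direction and lost the call at least once, the highest adjusted p among them being 0.190, for RP2 without mimic replicate 1. H2BC3 lost its call with each of the 8 arrays left out. The count of 107 depended on the arrays used. It was 72, 125, 30 and 23 without control replicates 1, 2, 3 and 4, 24, 26, 23 and 58 without mimic replicates 1, 2, 3 and 4, and 51 without control replicates 1 and 2 together.

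**Figure D2:**
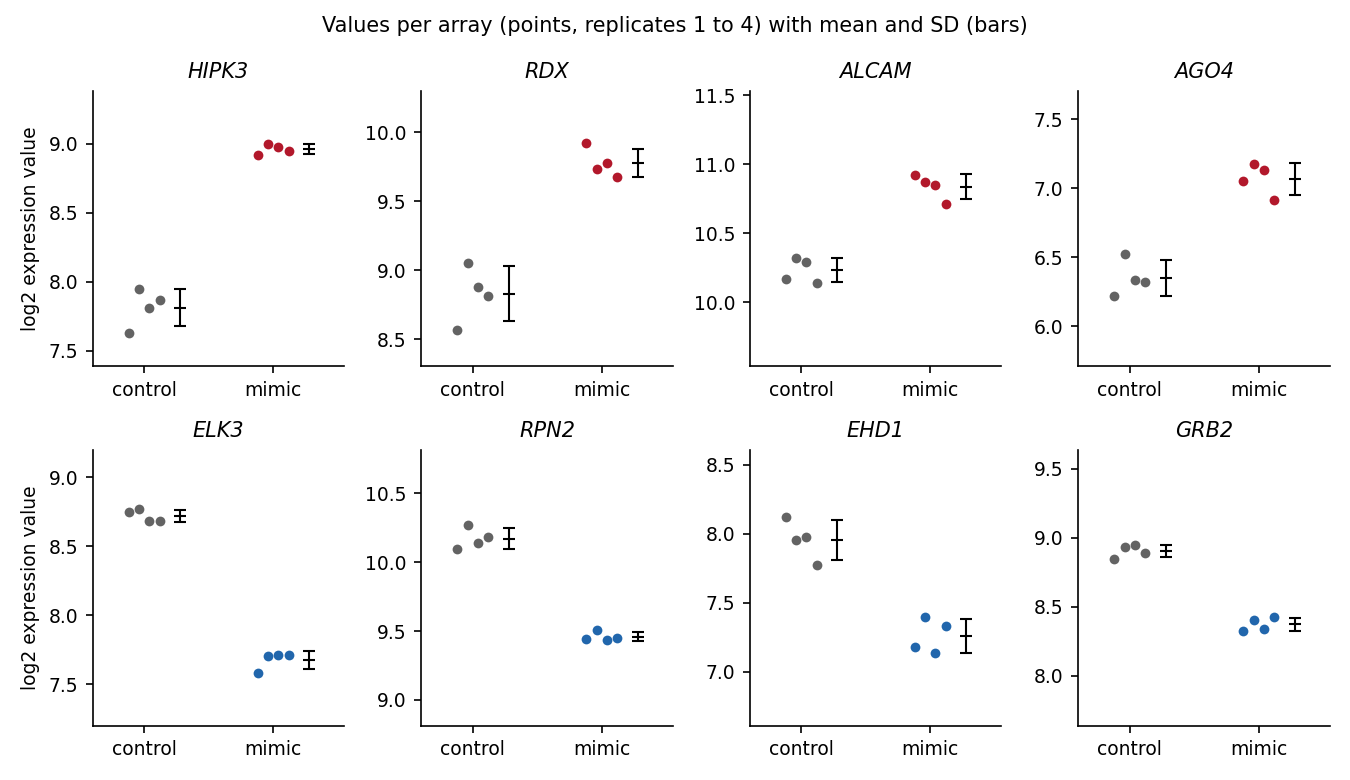
Log2 expression values of HIPK3, RDX, ALCAM, AGO4, ELK3, RPN2, EHD1 and GRB2 on each array (points), with the mean and SD of 4 arrays per group (bars) and a y axis of the same length in each panel. The mimic arrays lie above all control arrays in the top row, by 0.61 to 1.15 on average, and below them in the bottom row, by -0.53 to -1.04.

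Genes reported elsewhere as direct targets of miR-378 had values on both sides of 0, with 9 above and 10 below. Of 19 such genes tested, GRB2 and EHD1 were lower, ALCAM was higher and 16 did not pass. GRB2, the adaptor that links receptor tyrosine kinases to Ras, fell from 8.90 ± 0.05 (SD, n = 4) to 8.37 ± 0.05 (SD, n = 4), a log2 difference of -0.53 (SE 0.0609, adjusted p = 0.00512). EHD1 fell from 7.96 ± 0.14 (SD, n = 4) to 7.26 ± 0.12 (SD, n = 4), a log2 difference of -0.70 (SE 0.0900, adjusted p = 0.00866) on probe 7949264. ALCAM rose from 10.23 ± 0.09 (SD, n = 4) to 10.84 ± 0.09 (SD, n = 4), a log2 difference of 0.61 (SE 0.0729, adjusted p = 0.00555) on probe 8081431. The 16 others had values from -0.27 (TOB2) to 0.23 (GABPA), with GALNT7 at 0.23, CRAT at -0.21 and SUFU, an inhibitor of Hedgehog signalling, at 0.03. Adjusted over the list alone, 1 gene was higher and 3 were lower, TOB2 being the one added. ALCAM and EHD1 were put into this list from general knowledge of work on miR-378 that may have picked them on these same samples, so their places in this and in the adhesion and endocytosis lists are not independent evidence. The labels do not name ALCAM or EHD1. Apart from these genes only GRB2 passed, and it was lower. The list's median was -0.00 and its camera adjusted p was 0.839. EHD1 lost its call without mimic replicate 1, at an adjusted p of 0.05005.

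Of 23 histone genes that are transcribed during DNA replication, 22 had values below 0 in mimic minus control arrays, with a list median of -0.18 and a mean of -0.20 (SE over arrays 0.0451). The list was lower by camera with a preset correlation (adjusted p = 1.92e-09) and did not pass with an estimated correlation (adjusted p = 0.706) or by the directional test of fry (adjusted p = 0.0825). H2BC3 (-0.52, adjusted p = 0.0443) and H3C7 (-0.41, adjusted p = 0.0490) fell, and the other 21 did not pass. These genes are close copies of each other, and signal shared between their probes was not tested. Genes of the G1/S transition and DNA replication had 27 of 35 values below 0 and a median of -0.10, with 0 genes passing and 8 lower at an unadjusted p under 0.05. CDC25A, a phosphatase that opens the way into S phase, had a value of -0.29 (adjusted p = 0.140), CDT1 of -0.31 (adjusted p = 0.158) and cyclin E1 (CCNE1) of -0.26 (adjusted p = 0.180). Of 32 cytosolic ribosomal protein genes, 26 had values below 0, with a median of -0.05, and 0 passed while 3 were lower and 1 was higher at an unadjusted p under 0.05. The member with the smallest p was RPS19, at -0.26 (adjusted p = 0.189). In G2/M and mitosis genes 19 of 36 values were above 0, the median was 0.01, and CDC20 had the smallest p at -0.32 (adjusted p = 0.0626). With 0 genes of that list passing, 2 were higher and 5 lower at an unadjusted p under 0.05, and KIF11 (0.45) was the 1 higher and CDC20 among the 5 lower when adjusted over the list alone.

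By camera with a preset correlation 3 lists were lower, histones as given above, G1/S at adjusted p = 0.000244 and ribosomal proteins at 0.0455, and 0 of 29 lists were higher. With an estimated correlation 0 lists passed, at adjusted p = 0.768 for G1/S and 0.768 for ribosomal proteins, and 1 list was under 0.05 unadjusted. Fry's directional test passed 0 lists as well, with 4 under 0.05 unadjusted. Fry's mixed test, which asks whether members differ in either direction, passed 16 of the 29 lists. It does not compare a list with the other genes. Over all 18377 genes 2273 were under 0.05 unadjusted by limma's test, so passing the mixed test does not set a list apart. Among the 16 were ERBB, MAPK and PI3K signalling (adjusted p = 2.28e-05), where GRB2 alone passed by limma's test, and the reported targets (adjusted p = 5.44e-05). The reported targets include ALCAM and EHD1, which may have been picked on these same samples, so that value is not independent evidence. The mixed test was not repeated without ALCAM, EHD1 or GRB2, or on other splits of the arrays. Adjusted over the list alone, 9 histone genes and 4 G1/S genes were lower, against 0 ribosomal protein genes. Without control replicate 2 the camera adjusted p of the G1/S list was 0.121 and that of the ribosomal list 0.270. The ribosomal list was also over the threshold without control replicate 4 (0.142), mimic replicate 2 (0.0990) or mimic replicate 4 (0.390). The highest adjusted p of H2BC3 with an array left out was 0.170, without mimic replicate 3. H3C7 lost it in 7 of 8 cases and reached 0.187 without the same array. Control replicate 1 differed from the other controls by a median of 0.07 in the histone list, -0.12 in the G1/S list and -0.19 in the G2/M list.

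Among 22 genes of the microRNA pathway, AGO4 and TNRC6A rose and 0 fell. AGO4 went from 6.35 ± 0.13 (SD, n = 4) to 7.07 ± 0.12 (SD, n = 4), a rise of 0.72 (SE 0.0852, adjusted p = 0.00550). TNRC6A, a scaffold that joins Argonaute proteins to the deadenylation machinery, rose from 7.83 ± 0.14 (SD, n = 4) to 8.43 ± 0.08 (SD, n = 4), by 0.60 (SE 0.0808, adjusted p = 0.0124). Related genes did not pass: AGO1 stood at -0.08, AGO2 at -0.09, AGO3 at -0.00, TNRC6B at 0.16 and TNRC6C at 0.10. AGO3 changed its sign under a second quantile normalization, to 0.00. The list's mean was 0.07 and its median -0.00, with a camera adjusted p of 0.240. Adjusted over the list alone, AGO4 and TNRC6A were again the 2 genes higher. TNRC6A lost its call without control replicate 4 (adjusted p = 0.0641) and without mimic replicates 1 (0.0515) and 2 (0.0535). Control replicate 1 lay below the other controls in this list, by a median of -0.15.

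Signalling and stress lists held few genes that passed. In ERBB, MAPK and PI3K signalling, GRB2 fell and 36 of 37 genes did not pass, among them ERBB2 at -0.14 (adjusted p = 0.432). Adjusted over the list alone, the early response gene EGR1 (0.39) and PHLDA1 (0.25) were added as higher. OAS3, an interferon-induced sensor of double-stranded RNA, fell by 0.44 (adjusted p = 0.0269), and the other 37 interferon-stimulated genes did not pass. DNAJB9, a co-chaperone of the endoplasmic reticulum, rose by 0.45 (adjusted p = 0.0439), and 19 other genes of the unfolded protein response did not pass. OAS3 lost its call in 6 of 8 cases and DNAJB9 in 7 of 8 when an array was left out, with adjusted p up to 0.109 (without mimic replicate 1) and 0.177 (without mimic replicate 3). PDIA4 (-0.22) was lower when adjusted over the list alone. Among 33 adhesion genes ALCAM rose. Adjusted over that list alone, desmoplakin (DSP, 0.27) and ITGA2 (0.33) were added as higher and keratin 8 (KRT8, -0.23) as lower. In 29 genes of endocytosis and recycling EHD1 fell, and the clathrin adaptor gene AP2M1 (-0.30) was lower only when adjusted over the list alone. The TGF-beta list had 0 of 24 genes passing, and 3 higher and 4 lower when adjusted over the list alone. SMAD2 (0.45), TGFBR1 (0.24) and SKIL (0.31) were the ones higher, and BMP2 (-0.33), TGFBR2 (-0.26), ID1 (-0.28) and ID3 (-0.27) the ones lower.

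No gene passed in 21 of the 29 lists. Together they held 511 genes, of which 32 were higher and 47 lower at an unadjusted p under 0.05, and 0 passed by a plain equal-variance test. Outside the lists already described, those passing when adjusted over the list alone were CXCL8 and STARD4, both higher, and BAK1, lower. The angiogenesis and NF-kappa-B lists were led by the chemokine gene CXCL8 at 0.39 (adjusted p = 0.0948), and VEGFA stood at 0.17 (adjusted p = 0.382). In apoptosis the smallest p was that of BAK1 at -0.38, in p53 targets TIGAR at 0.41, in hypoxia and glycolysis P4HA1 at 0.38 and in the respiratory chain and citrate cycle IDH3A at 0.23. Cholesterol synthesis was led by STARD4 at 0.46, fatty acid metabolism by ACADVL at -0.21, the ATF4 response by SESN2 at -0.37 and the matrix list by MMP1 at 0.38. Hedgehog genes were led by CDON at 0.12, homologous recombination by FANCE at -0.29 and the markers of ovarian carcinoma by MSLN at -0.34. Camera's adjusted p was 0.240 or more in the 26 lists that did not pass. Median, mean and test differed in sign in 9 of those 26.

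**Figure D3:**
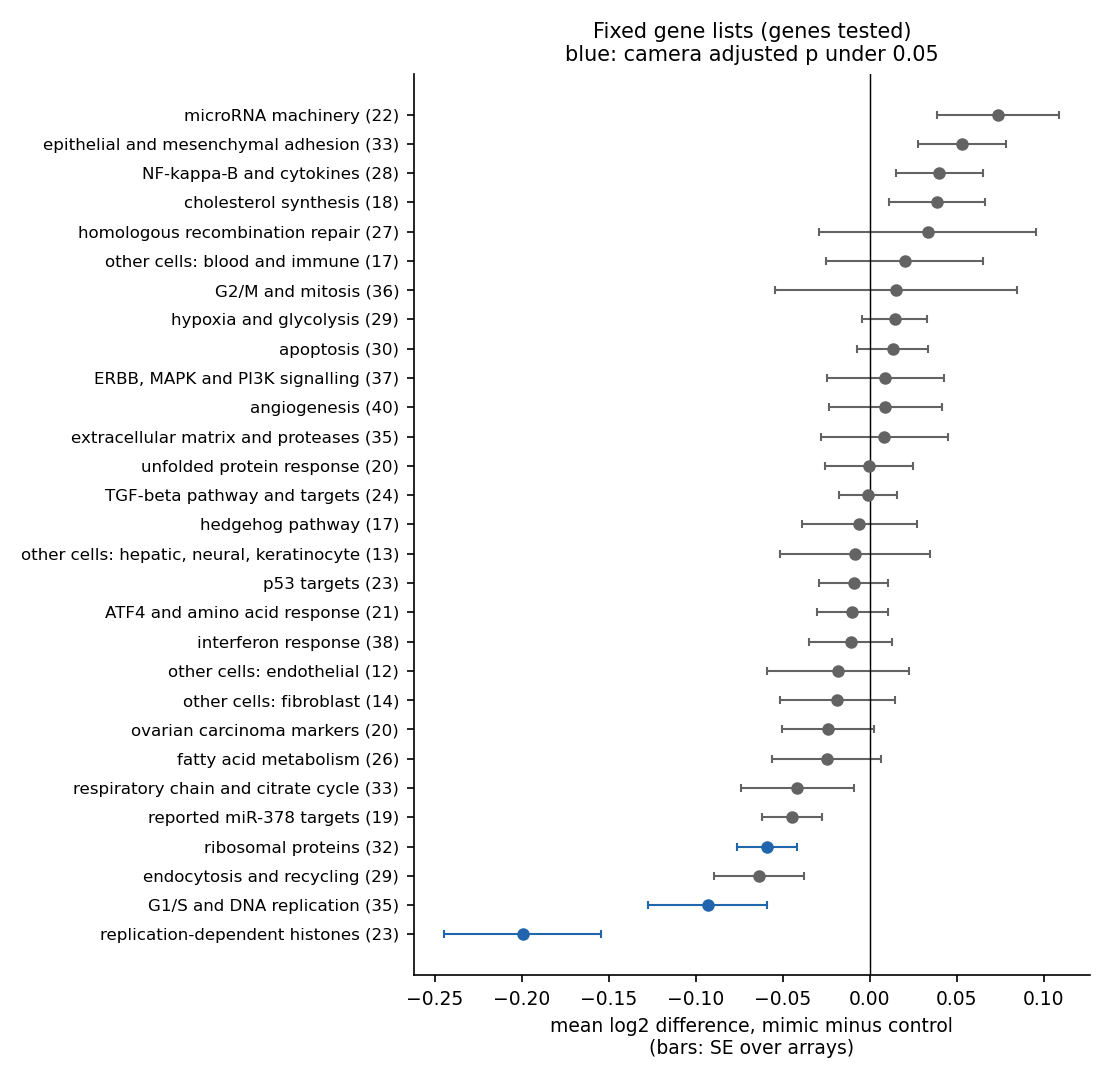
For each of the 29 fixed lists, the point is the mean log2 difference of its genes (x axis, mimic minus control) and the bar the SE over arrays, with the number of genes tested in parentheses. Histones lie at -0.20, G1/S genes at -0.09 and ribosomal proteins at -0.06, and these 3 are the lists whose camera adjusted p with a preset correlation was under 0.05; with an estimated correlation 0 of the 29 were.

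Most markers of other cell types stood low on these arrays. Of 56 such genes 11 reached the level of 5.22 used as the expression limit. The highest mean over the arrays was 8.39 in the blood and immune genes, with PTPRC at 6.88. It was 6.92 in the endothelial, 6.42 in the fibroblast and 6.10 in the remaining markers. Median levels were 4.11 for 17 blood and immune genes, 4.06 for 12 endothelial, 4.30 for 14 fibroblast and 4.46 for 13 hepatic, neural and keratinocyte genes. By limma's test 0 of the 56 passed, 1 was under 0.05 unadjusted, and 0 passed by the plain equal-variance test. The members with the smallest p were PTPRC (0.19), EMCN (-0.10), FAP (0.19) and SERPINA1 (-0.16). ERBB2, which SKOv3 cells express strongly, had a log2 level of 11.33 ± 0.06 (SD, n = 4) in control and 11.18 ± 0.09 (SD, n = 4) in mimic arrays. Control replicate 1 stood apart from the other arrays. Its score on the first principal component, which held 42.4% of the variance, was -28.7, and the other 7 arrays lay between -4.59 and 13.4. This array exceeded the other controls by a median of 0.14 in the blood and immune genes, 0.17 in the endothelial, 0.13 in the fibroblast and 0.11 in the remaining markers. Over all genes its difference from the other controls was 0.08, 0.13, 0.00 and -0.07 in 4 equal bins of level, from the lowest to the highest.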

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

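Predictions for the tests below were written before their results were seen, except that the test of the splits of the arrays left without control replicate 1 was chosen after the count of genes without that array had been seen. Within each group of 4 arrays, values were examined for 1 array whose gap to the nearest other exceeded Dixon's 95% critical value; 9 of 120 groups examined met this, where chance gives about 1 in 20.

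Control replicate 1 and control replicate 2, at opposite ends of the first principal component, account for 5 of these. In control replicate 1 the log2 value of ERLIN1 was 7.88 against 8.35 to 8.43 in the other controls, and that of SESN2 was 7.01 against 6.55 to 6.62. In control replicate 2 TIGAR stood at 5.65 against 5.14 to 5.19, OAS3 at 6.41 against 6.25 in the others and DNAJB9 at 5.35 against 5.08 to 5.11. Among mimic arrays, ELK3 was 7.58 in replicate 1 against 7.70 to 7.71, TNRC6A was 8.54 in replicate 2 against 8.37 to 8.40, and PPARGC1B was 6.46 in replicate 4 against 6.07 to 6.12. The median of all probes was 5.17 in mimic replicate 4 against 5.11 to 5.12 in the other mimic arrays. Of 9559 probes outside the genes tested, 6 passed, 1 higher and 5 lower, with 735 under 0.05 unadjusted; all 6 are unnamed here. Probes 8171111 and 8177003, chosen after their values were seen, had identical values and a log2 difference of -0.72.

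The first pattern weighed is the set of 107 genes that changed. Chance is argued against. Of the 35 splits of the 8 arrays, 1, the real one, gave as many calls, and the highest other split gave 2. The real split always counts, so 1 of 35 is the smallest share this test can give, and chance is not excluded. Without control replicate 1, 72 genes passed, 68 of them among the 107, and 1 of the 35 splits of the 7 arrays left, the real one, gave as many calls, the highest other split giving 2; this argues against that array as the cause for the 68. For the other 39 genes it cannot be told apart. All 107 (100%) kept at least 0.5 of their log2 difference without it, with ratios from 0.788 to 1.15, a bound set in advance that decides nothing, since genes that pass with groups that do not overlap could hardly have missed it, and a call can also be lost through fewer arrays. An unequal signal range after the authors' normalization is argued against too. The interquartile range of all probes was 3.69 to 3.87 in control and 3.73 to 3.81 in mimic arrays, so the groups overlapped in range. Of the 107 genes 97.2% passed again after a second quantile normalization, with 0.959 to 1.04 of their log2 difference. With ranges so alike that step had little room to move them. Subtracting array medians, which shifts arrays and leaves their range, kept 46 of the 107 calls; the log2 differences were 0.998 to 1.00 of those before, and the median SE rose from 0.0773 to 0.0888, so these calls ended through a wider spread. An effect of the mimic may then account for the 68 genes, as a hypothesis from the same data; direct pairing with miR-378 was not tested, and a handling difference shared by the arrays of a group stays open.

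The second pattern is the lower histone and G1/S lists. Chance is not excluded for the list calls: 12 of 35 splits called as many lists as the real 3, and the highest other split called 9, which points to shared movement of list genes between arrays. Control replicate 1 alone is argued against. The mean difference of the pooled lists was -0.146 without it (within 2 SE, -0.217 to -0.0758) and -0.135 with it. In the G1/S list its mean relative to all arrays was -0.0371, below the other controls, so leaving it out could only widen that difference. In the histone list it was 0.145, so the pooled value does not weigh that list on its own. With any single array left out, the median of the histone list lay between -0.233 and -0.162, and its camera call with a preset correlation stayed. Control replicate 2 was the highest array in both lists, at 0.125 in G1/S and 0.153 in histones. It was not weighed in the pooled lists, and without it the camera adjusted p of the G1/S list was 0.121. For the histone list, a lower yield of RNAs without a poly(A) tail cannot be told apart. The 107 small nucleolar and nuclear RNA genes averaged -0.0439 with bounds of -0.157 to 0.0690, too wide to decide. They were set against the histone list only, not against the G1/S list. Fewer dividing cells cannot be told apart either, as the G2/M list averaged 0.0150 with bounds of -0.124 to 0.154.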

How the results depend on the processing

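Of 17 alternatives for single genes 13 can move a log2 difference, and in these 0 of the 30 named genes that passed reversed; 6 (ELK3, HIPK3, NHSL3, RPN2, TUFT1 and YWHAH) passed in all 17, and 12 named genes that had not passed did so in at least 1. Against 65 genes higher and 42 lower, a second quantile normalization gave 105 and 58 (104 of the 107 genes shared), subtracting medians 25 and 22 (46 shared), leaving out dim genes 123 and 97, a trended and robust eBayes 130 and 99 and array weights 262 and 187. The mean of all probes gave 64 and 40, every probe on its own 30 and 26, the plain equal-variance test 23 and 19, a 1.5-fold minimum 17 and 12, an adjusted p under 0.01 13 and 9, and leaving out control replicates 1 and 2 together, added after seeing the data, 39 and 12. With single arrays left out the counts ran from 13 to 94 higher and from 8 to 31 lower. Fewer arrays, fewer genes tested or stricter limits are part of some of these settings; for the others the cause was not tested. With the replicate number as a block, which cannot move a difference here, 4 and 4 genes passed, and 22 of the 30 named genes were over the threshold. The labels do not say whether the numbers pair the arrays. Same-numbered arrays had residual correlations of -0.34, 0.05, 0.03 and -0.03, and 1 of 8 arrays correlated best with its own number. These values show no pairing but cannot exclude it. Lists lower numbered 3, but 0 with an estimated correlation or fry's directional test, and 1 to 4 with single arrays left out; lists higher numbered 0 throughout. The ribosomal list was over the threshold with medians subtracted, dim genes left out, the block, or control replicates 1 and 2 left out. PPARGC1B, not passing, ranged from -0.0839 to 0.0640 with single arrays left out, and reached 0.131 over all 17 alternatives. SUFU, not passing, ranged from -0.0154 to 0.0673 with single arrays left out. It stood at -0.00526 with array weights and -0.0236 without control replicates 1 and 2. Values near the background carry least information; the table gives no signal over background per probe. Seed-match settings and a pseudocount were not run, since sequences were not used here and the values were on a log scale.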

Other observations

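The genes in this paragraph were chosen after their values were seen, from the 107 that passed, and are given as values. ERLIN2, the partner of ERLIN1 in the endoplasmic reticulum membrane, rose by 0.48. Talin (TLN1), which links integrins to actin, rose by 0.60, LSM14A, an RNA-binding protein of processing bodies, by 0.60, SWAP70 by 0.58 and the receptor chain IL10RB by 0.57. ATL3 (0.51), GOLGA4 (0.60), BLZF1 (0.45), SCAMP1 (0.48), STX2 (0.43), ACVR2A (0.54) and the thrombin receptor gene F2R (0.43) rose as well. The protease gene ADAM17 rose by 0.41 and DDX3X by 0.33. Enrichment of any function was not tested for these genes.

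Genes that fell, chosen in the same way after their values were seen, are given as values too. POLA2, a subunit of DNA polymerase alpha, had a log2 difference of -0.39, the histone chaperone gene ASF1B of -0.41, UHRF1, which helps maintain DNA methylation, of -0.47, CCNF of -0.32, the deacetylase gene HDAC3 of -0.48 and the histone gene H2AC21 of -0.44. RUBCN, a regulator of autophagy, stood at -0.58, BCL9, a cofactor of beta-catenin, at -0.44 and VANGL1 at -0.38. Enrichment was not tested here either, and 0 of 35 genes passed in the fixed list of G1/S and DNA replication. Of the 2 small RNA or LOC symbols that passed, MIR21 rose by 0.46 and LOC728024 by 0.61. VMP1, which overlaps MIR21, stood at 0.15 and did not pass. Whether the MIR21 probe reads the mature microRNA was not tested, so its rise is not a measure of mature miR-21.

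One hypothesis was that the mimic competes with the cells' own microRNAs and so raises their targets, with its prediction written before the result was seen. The 49 tested targets of let-7, miR-21 and miR-17 that were listed for this had a median log2 difference of 0.0196, with 95% bootstrap bounds over genes of -0.0291 to 0.0581. Of these targets 0 passed as higher and 1, a let-7 target, passed as lower. The bound set in advance was 0.260, a share of the median rise of 0.52 among genes that passed. The median lay under it, but this decides nothing, since genes chosen for passing had rises of at least 0.33, which a list not chosen in that way could hardly match, and the bootstrap leaves out the spread between arrays. Competition as the cause of the rises cannot be told apart: the pooled targets had a camera p of 0.509 with an estimated correlation. By list, camera p was 0.116 for 22 let-7 targets, 0.0237 for 13 miR-21 targets and 0.312 for 15 miR-17 targets, and 0.0895 for miR-21 with an estimated correlation.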
